A study of Mus musculus with 58 samples.

How the data were processed

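The series holds 58 libraries from liver of C57BL/6 mice labelled L-Rpa1 WT or KO: 6 of RNA-seq, 12 of ATAC-seq and 40 of CUT&Tag. Per the labels, RNA was extracted with Trizol from frozen liver and made into libraries with the Illumina TruSeq kit, and nuclei were used for ATAC-seq (Vazyme TruePrep) and CUT&Tag (Novoprotein NovoNGS). The labels give no age, sex, diet or deletion strategy. Nothing in them says that replicates come from separate animals, and if they do not, the p-values measure only the spread between these samples. Genotype, assay, antibody and replicate number were taken from the labels. Titles of the RPA1 libraries spell the target PPA1, while their antibody field names RPA1, which was used.

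The deposited RNA-seq table holds raw counts per Ensembl gene for the 6 libraries, with exon coordinates on GRCm38; the program that counted is not given in the sources used here. The deposited peak lists, 1 per ATAC-seq or CUT&Tag library, are in the narrowPeak format of MACS2 and give for each peak a ratio, its fold enrichment over the background of its own library. They also give, as deposited, -log10 p and -log10 q values of the peak within its own library. The submitters' processing notes name Bowtie2, MACS2 and the builds mm10 and GRCm38; versions, settings, any control library and any blacklist are not given in the sources used here. The smallest -log10 p in a CUT&Tag list was 5.0002 and the smallest -log10 q in an ATAC-seq list 1.3122, so lists were made with different thresholds for these assays. Fold enrichment and p depend on the depth of each library, so peaks were compared by presence and not by score. Raw reads and read coverage were not used here, so no amount of signal per region was measured.

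The count table lists 55401 genes, of which 55141 identifiers were matched to a symbol; 107 symbols occur more than once, and genes were therefore handled by identifier. Total counts were 4810898, 6307835 and 6427296 in WT and 6429746, 5857031 and 5313293 in KO. The 10 most abundant genes took 18.0% to 21.9% of the counts of a library. A group at 0 counts was set to a floor of 3 counts over the group, and the fold is then a lower bound; intervals and floors cover counting error only. In data simulated on these counts, 100 genes were changed by a log2 fold change of 1 and 100 by 2. The RNA-seq test found 66% and 97% of them, with 8.94% of 179 calls false. Far more genes were called in the data, so these shares need not hold there. Applied to 5000 simulated regions, the presence rules found 98.7% of KO-specific and 99.3% of WT-specific regions in the ATAC-seq design (1 false region), and 92.7% and 92.0% in the CUT&Tag design (7 false regions). Simulated shared regions were present in most libraries, whereas 15555 of 47149 H3K4me3 regions in the data were present in 1 library only. Splits of the H3K4me3 libraries that mix the genotypes gave a median of 245 specific regions. The false counts of the simulation therefore do not carry over to the data.

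RNA-seq was tested with edgeR 4.0.16 (quasi-likelihood F-test, TMM scaling, filterByExpr with a minimum count of 10) in R 4.3.3, KO against WT, on 12940 genes, with Benjamini-Hochberg adjustment and a threshold of 0.05. Tests were two-sided unless stated. TMM factors were 0.870 to 0.902 in WT and 1.03 to 1.22 in KO. CPM values are per library size scaled by TMM, and values after ± are SD. Gene lists, 33 in all, were written from general knowledge of the liver before the data were examined, as were the tests, the rule for named genes and 36 alternatives; 4 further alternatives and 6 further lists were chosen after seeing the data. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists. Camera was repeated with an estimated correlation, and fry was run beside it. Camera asks whether the genes of a list move more than other genes. By contrast, fry asks whether they move 1 way on balance, without a comparison with other genes. Alternatives for the counts were DESeq2 1.42.0 size factors, the DESeq2 test, limma-voom, no filter, a mean count of at least 10, library size without composition scaling (chosen after seeing the data), a replicate block, an absolute log2 fold change of at least 1, and leaving out each library.

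Genes were named by rule: Rpa1, Rpa2, Rpa3, Hnf4a and Ppara; the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 1 and no overlap between the 3 WT and 3 KO values; and up to 4 genes per list with the smallest p. Gene models without a symbol and predicted pseudogenes were left out of the largest changes. Regions were named at promoters of called genes, up to 3 per assay and direction with the largest change in RNA, and at specific promoters of genes named from RNA-seq. Some genes and regions that the rule names are not reported here. Genes of the imprinted, male-biased and female-biased lists were named after their values were seen.

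Peaks of all libraries of an assay were merged into regions, and a library was counted as having a region when a peak overlapped it by at least 1 bp (alternative: peaks covering at least 50% of the region). ATAC-seq regions were KO-specific when present in at least 5 of 6 KO and at most 1 WT library, CUT&Tag regions when present in 3 KO and 0 WT libraries, and WT-specific by the mirror rule. Promoters were windows of 1 kb (alternative 2.5 kb) on either side of the outermost annotated start of a gene. Number of peaks, covered length, share at promoters and promoter occupancy of lists relative to all expressed genes were compared by exact permutation of the genotype labels, whose smallest possible p is 0.1 for 3 against 3 and 0.00216 for 6 against 6 libraries. Similarity was the Jaccard index of covered base pairs, tested one-sided. Further alternatives were a -log10 q of at least 5, lists shortened to the length of the shortest by p, and regions without a rabbit IgG peak. All contigs in place of chromosomes 1 to 19, X and Y were another. ATAC-seq was also taken without the libraries whose file names carry another code, read here as that of another sequencing run. RPA1 overlaps carry exact binomial 95% intervals and were set against 100 shuffles of the peaks on their chromosomes. Results of models were compared with all 10 splits of 6 libraries, or with 100 splits of the 12 ATAC-seq libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Motifs were not analysed here.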

Results

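Liver tissue of C57BL/6 mice labelled L-Rpa1 WT or L-Rpa1 KO was profiled in 58 libraries. Rpa1 encodes the large subunit of replication protein A (RPA), the complex that binds single-stranded DNA during replication and repair. RNA-seq counted transcripts in 6 libraries, 3 per genotype. ATAC-seq, in which a transposase inserts adapters into open chromatin, was run on 12 libraries, 6 per genotype. CUT&Tag, in which the transposase is brought to an antibody bound to chromatin, gave 40 libraries. Antibodies against the histone marks H3K4me3, H3K27ac and H3K9ac, against RNA polymerase II (Pol II) and against the hepatocyte transcription factors HNF4A and PPARa were used in 3 libraries per genotype. RPA1 was profiled in 1 library per genotype, and mouse and rabbit IgG controls in 1 WT library each. The title of the series names chromatin organisation and lipid metabolism in the liver as its subject. Total RNA-seq counts ranged from 4810898 to 6427296 in WT and from 5313293 to 6429746 in KO, and ATAC-seq peak lists held 78875 to 107237 peaks.

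The targeted gene was read first. Rpa1 (chromosome 11, 75298166 to 75348324) had 24.96, 28.29 and 25.09 CPM in WT replicates 1 to 3 and 31.25, 21.69 and 23.73 CPM in KO replicates 1 to 3. Its log2 fold change was -0.03 (SE 0.15, edgeR adjusted p = 0.903), with 26.1 ± 1.89 CPM in WT and 25.6 ± 5.03 CPM in KO (SD, n = 3). The counts are per gene and the labels do not say which part of Rpa1 was deleted, so this value does not check the genotype labels, and KO and WT below mean libraries labelled so. Rpa2, the middle subunit of the complex, rose from 4.89 ± 2.06 to 12.9 ± 2.25 CPM (log2 fold change 1.37, SE 0.27, edgeR adjusted p = 0.002). Rpa3, the small subunit, rose, with a log2 fold change of Rpa3 of 0.63 (SE 0.21, edgeR adjusted p = 0.0328). The Rpa3 call was lost with DESeq2 (adjusted p = 0.128), with limma-voom (adjusted p = 0.0515) and without WT replicate 1 (0.0791), WT replicate 2 (0.0685), WT replicate 3 (0.0864), KO replicate 2 (0.122) or KO replicate 3 (0.07). Hnf4a, which encodes a transcription factor central to hepatocyte gene expression, fell from 1238 ± 204 to 661 ± 201 CPM (log2 fold change -0.91, SE 0.22, edgeR adjusted p = 0.00543). Ppara, which encodes the fatty acid sensing nuclear receptor, fell from 305 ± 30.4 to 151 ± 19.7 CPM (log2 fold change -1.01, SE 0.13, edgeR adjusted p = 0.000144).

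Livers labelled KO differed from WT in a large part of the transcriptome. Of 12940 genes tested, 3328 were higher and 2829 lower in KO at an edgeR adjusted p under 0.05, so 54.1% of the called genes were higher. H19, an imprinted non-coding RNA of fetal liver, rose from 1.41 ± 0.602 to 11353 ± 1341 CPM (SD, n = 3; log2 fold change 13.00). Igf2, its neighbouring fetal growth factor gene, had no count in WT and was at least 154-fold higher in KO. The sulfotransferase genes Sult2a1, Sult2a2 and Sult2a5 also had no WT count and were at least 576-fold, 233-fold and 82.4-fold higher, each bound taken against 3 counts over the WT group. Ypel4 (at least 35.0-fold), Krt20 (at least 34.8-fold), Scube3 (at least 33.5-fold), Amn (at least 32.2-fold) and Ly6d (log2 fold change 8.19) completed the 10 largest rises by fitted change. For genes without WT counts the fitted change, and so their rank, depends on the prior count, and genes with a measured rise above these bounds can lie outside the 10. Sult2a2 and Sult2a5 are close copies of Sult2a1, so the values of single members are uncertain. With library size scaling in place of composition scaling, the median of all genes moved from 0.01 to 0.37, and 5524 genes were called higher and 1163 lower (82.6% higher).

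The largest falls were in Mup genes and a steroid dehydrogenase gene. Mup7, which encodes a major urinary protein, fell from 618 ± 425 to 0.540 ± 0.810 CPM (SD, n = 3; log2 fold change -10.34, SE 0.95). Hsd3b5, a steroid dehydrogenase gene, fell from 224 ± 53.1 to 0.191 ± 0.228 CPM (log2 fold change -9.98, SE 0.37). The other 8 of the 10 largest fitted falls were Mup16 (-8.91), Mup11 (-8.49), Mup14 (-8.32), Mup21 (-7.41), Mup15, Mup8, Mup1 (-6.98) and Mup3 (-6.89, from 9315 ± 913 to 79.0 ± 83.8 CPM). Mup15 and Mup8 had 2 and 3 counts over the KO group, ratios of KO over WT of 0.0013 (exact 95% counting interval 0.00016 to 0.0047) and 0.0066 (0.0014 to 0.020). Mup genes are near-identical copies on chromosome 4, so the values of single members are uncertain. The Mup1 call was lost with limma-voom (adjusted p = 0.0834). WT replicate 1 held 262 CPM of Mup1 against 20.3 and 19.5 CPM in WT replicates 2 and 3.

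**Figure D1:**
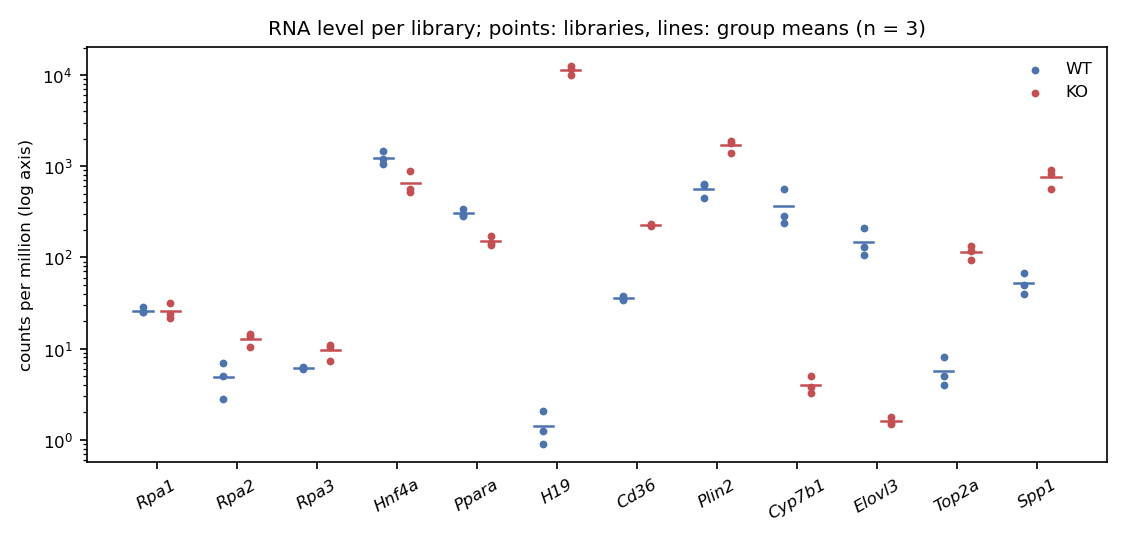
CPM (log axis) of named genes in each of the 3 WT and 3 KO RNA-seq libraries, each point being 1 library. Rpa1 lies at the same level in both genotypes, between 21.7 and 31.3 CPM, while H19, Cd36, Top2a and Spp1 are higher and Cyp7b1, Elovl3 and Ppara are lower in every KO library.

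Genes of cell division and DNA synthesis were higher in KO. In the cell cycle and mitosis list, 29 of 30 measured genes rose and 1 fell (29 and 1 adjusted over the list alone), with a median log2 fold change of 4.09 (camera adjusted p = 2.49e-14, and adjusted p = 0.259 with an estimated correlation). Ccna2, the cyclin of S and G2 phase, rose by 4.53, Top2a by 4.36, Tpx2 by 4.46 and the G1 cyclin gene Ccnd1 by 3.43. Of 32 DNA repair and replication genes, 25 rose and 1 fell (26 and 1 adjusted over the list alone; median 1.61, adjusted p = 4.01e-08, and adjusted p = 0.259 with an estimated correlation). They included the replicative helicase genes Mcm5 (4.32), Mcm6 (2.74) and Mcm3 (2.35). The p53 and DNA damage response list had 23 of 29 genes higher and 1 lower (23 and 1 adjusted over the list alone; median 1.29, adjusted p = 4.01e-08, and adjusted p = 0.259 with an estimated correlation), among them Ckap2 (5.20), Eda2r (4.25) and Phlda3 (4.07). Psrc1 had 2 counts over the WT group and 346 over the KO group, a ratio of 134 with an exact 95% counting interval of 36.7 to 1108. Psrc1 and Ckap2 are also genes of the mitotic spindle. Immediate early genes rose in 9 of 14 cases and fell in 1 (9 and 2 adjusted over the list alone; median 1.25, adjusted p = 0.0054, and adjusted p = 0.259 with an estimated correlation), among them Atf3 (4.62), Egr1, Klf6 (2.60) and Jun (1.16).

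Genes of fetal liver and liver tumours rose without exception among those measured. All 19 measured members of that list were higher in KO (19 adjusted over the list alone), with a median log2 fold change of 4.60 (camera adjusted p = 2.11e-11, and adjusted p = 0.259 with an estimated correlation). H19 and Ly6d are given above. Prom1, which encodes a progenitor cell surface protein, rose by 4.94 (54.1 ± 11.4 against 1.74 ± 0.219 CPM; SD, n = 3), and Golm1, which encodes a Golgi protein, by 3.45.

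Hepatocyte genes fell. Of 34 measured genes of hepatocyte identity and secreted plasma proteins, 25 fell and 0 rose at an edgeR adjusted p under 0.05 (28 and 0 adjusted over the list alone), with a median log2 fold change of -0.81 (camera adjusted p = 1.39e-08, and adjusted p = 0.282 with an estimated correlation). They included the protease inhibitor gene Serpina1c (-2.31) and the coagulation genes F7 (-1.54) and Proc (-1.29). The urea cycle and amino acid list had 17 of 28 genes lower and 1 higher (18 and 1 adjusted over the list alone; median -0.53, adjusted p = 5.8e-05, and adjusted p = 0.282 with an estimated correlation), with Prodh (-1.79), Tat (-1.66), Gnmt (-1.21) and Asl (-1.17). Gluconeogenesis and glycogen genes fell in 12 of 15 cases and rose in 2 (12 and 2 adjusted over the list alone; median -0.95, adjusted p = 0.00103, and adjusted p = 0.282 with an estimated correlation), including the glycogen targeting subunit gene Ppp1r3b (-2.37), Tat (given above), Pygl (-1.19) and Slc37a4 (-1.10). Of 23 acute phase genes 15 fell and 2 rose (15 and 2 adjusted over the list alone; median -0.65, adjusted p = 0.000729, and adjusted p = 0.282 with an estimated correlation). Saa4 (-3.46), Orm1 (-1.53) and Lbp (-0.95) fell and Lcn2 (3.65) rose. Of 16 circadian clock genes 11 fell and 0 rose at an edgeR adjusted p under 0.05 (11 and 0 adjusted over the list alone; median -0.86, adjusted p = 0.00103), with the clock output genes Tef (-1.36) and Hlf (-1.11) and the clock repressors Per2 (-0.89) and Cry2 (-0.81); its adjusted p = 0.259 with an estimated correlation. No fall of these 5 medians turned positive with library size scaling, where the urea cycle list had 13 genes lower and 5 higher (median -0.18) and the acute phase list 10 and 3 (median -0.29).

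Lipid genes, the subject of the series title, moved in different directions by pathway. The PPAR-alpha target list rose, with 14 of 30 genes higher and 1 lower (14 and 3 adjusted over the list alone; median 0.54, camera adjusted p = 0.0216), although Ppara itself fell. With library size scaling 20 rose and 1 fell (median 0.87). Its examples were Cidec (3.89), which encodes a lipid droplet protein, the thioesterase gene Acot2 (3.73), the fatty acid transporter gene Cd36 (2.67, from 35.5 ± 2.15 to 226 ± 6.48 CPM; SD, n = 3) and Ucp2 (2.13). This list call was lost without KO replicate 3 (adjusted p = 0.175, with 13 genes higher and 5 lower), and its adjusted p = 0.548 with an estimated correlation. The fatty acid and triglyceride synthesis list fell, with 11 of 21 genes lower and 1 higher (11 and 1 adjusted over the list alone; median -0.37, adjusted p = 0.0134; adjusted p = 0.472 with an estimated correlation). Thrsp, a lipogenic regulator gene, fell by 5.42 on the log2 scale, the acyltransferase gene Dgat2 by 1.44 and Acss2 by 1.10, while the elongase gene Elovl5 rose by 1.56. With library size scaling, 6 genes of this list rose and 6 fell (median -0.01).

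Bile acid and lipoprotein genes were lower in KO. Of 20 bile acid synthesis and transport genes 14 fell and 2 rose (14 and 2 adjusted over the list alone; median -0.90, camera adjusted p = 0.000235, and adjusted p = 0.259 with an estimated correlation). Cyp7b1, the oxysterol hydroxylase gene of the alternative bile acid pathway, fell from 362 ± 173 to 3.99 ± 0.885 CPM (SD, n = 3; log2 fold change -6.52) and the uptake transporter gene Slco1a1 by 6.12 on the log2 scale, while the efflux transporter gene Abcc4 rose by 2.94. Of 20 lipoprotein genes 14 fell and 2 rose (14 and 2 adjusted over the list alone; median -0.56, adjusted p = 0.00431, and adjusted p = 0.282 with an estimated correlation). With library size scaling 7 lipoprotein genes fell and 4 rose (median -0.20). Lipc (-0.89) and Lcat (-0.88), which encode plasma lipid enzymes, fell, and Apoa4 and Tm6sf2 (1.02) rose.

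Other lipid lists were not called. Fatty acid oxidation had 6 of 30 genes higher and 4 lower (5 and 4 adjusted over the list alone; camera adjusted p = 0.94). With library size scaling 17 rose and 1 fell (median 0.37). Its median of 0.02 and mean of 0.25 were positive while camera gave the direction as down. Without KO replicate 3 the counts were 5 higher and 9 lower. Ehhadh, a peroxisomal oxidation gene, rose by 2.29 and Cyp4a31 by 2.65, whereas its close copy Cyp4a32 fell by 2.55 on the log2 scale, so both Cyp4a values are uncertain. Ketogenesis had 3 of 6 genes higher and 1 lower (3 and 2 adjusted over the list alone; 3 and 2 without KO replicate 3; median 0.39, adjusted p = 0.594), with the ketone and lactate transporter gene Slc16a1 at 1.79 and Bdh1 at 1.01. Cholesterol synthesis had 8 of 24 higher and 4 lower (8 and 4 adjusted over the list alone; 15 and 2 with library size scaling and 5 and 3 without KO replicate 3; median 0.13, adjusted p = 0.477), with Hmgcs1 at 2.00 and Sqle at 1.26 against Tm7sf2 at -1.08. Lipid droplet proteins had 3 of 13 higher and 2 lower (3 and 2 adjusted over the list alone; adjusted p = 0.936), with Plin2 at 1.59 and Plin4 at -1.04. The median was -0.16, the mean 0.25 and the camera direction down. The median was 0.21 with library size scaling, and without KO replicate 3 the counts were 3 higher and 4 lower.

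Energy metabolism moved little. Oxidative phosphorylation genes fell in 9 of 30 cases and rose in 0 at an edgeR adjusted p under 0.05 (4 and 0 adjusted over the list alone), with a median log2 fold change of -0.22 (camera adjusted p = 0.00905; adjusted p = 0.594 with an estimated correlation). Sdha, a subunit gene of complex II, fell by 0.64 on the log2 scale. This direction turned with library size scaling (median 0.13, 4 higher and 0 lower), the call of Sdha was lost there (adjusted p = 0.0743), and the adjusted p of the list oxidative phosphorylation was 0.0671 without KO replicate 1, where the call was lost. The tricarboxylic acid cycle list was not called, with 4 of 18 higher and 7 lower (4 and 7 adjusted over the list alone; median -0.15; 7 higher, 0 lower and a median of 0.20 with library size scaling; adjusted p = 0.566), Idh3a at 0.86, Idh2 at 0.86 and Ogdh, a subunit gene of the oxoglutarate dehydrogenase complex, at -0.53. The log2 fold change of Ogdh was -0.17 with library size scaling, where its call was lost (adjusted p = 0.25).

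Markers of bile duct cells, stellate cells and macrophages were higher in KO. All 13 measured cholangiocyte markers rose (13 adjusted over the list alone; median 2.63, camera adjusted p = 2.14e-07, and adjusted p = 0.259 with an estimated correlation), including Epcam (4.60) and Krt19 (2.63). Of 22 stellate cell and fibrosis markers 19 rose and 0 fell (19 and 0 adjusted over the list alone; median 1.99, adjusted p = 3.78e-09, and adjusted p = 0.259 with an estimated correlation). Col1a1, the type I collagen gene, rose from 19.8 ± 0.624 to 169 ± 41.0 CPM (SD, n = 3; log2 fold change 3.09), Lum by 3.00 and Mmp2 by 2.67. Of 23 Kupffer cell and macrophage markers 19 rose and 2 fell (21 and 2 adjusted over the list alone; median 1.01, adjusted p = 1.93e-06, and adjusted p = 0.259 with an estimated correlation), led by Gpnmb (6.44), Trem2 (4.15), Spp1 (3.86, also on the cholangiocyte list) and Marco (2.25). Sinusoidal endothelial markers were not called, with 1 of 15 higher and 5 lower (1 and 4 adjusted over the list alone; 0 and 3 without KO replicate 3; median -0.06; 4 higher, 1 lower and a median of 0.29 with library size scaling; adjusted p = 0.375); Lyve1 fell by 1.18 on the log2 scale.

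Genes of interferon signalling, inflammation and neutrophils rose as lists, and lymphocyte and erythroid markers were not called. Of 30 interferon and cytosolic DNA sensing genes 15 rose and 0 fell at an edgeR adjusted p under 0.05 (15 and 0 adjusted over the list alone; median 0.58, camera adjusted p = 0.00184; adjusted p = 0.385 with an estimated correlation), with the DNA sensing adaptor gene Tmem173 (1.98), Cxcl10 (1.99) and Oasl2 (1.19). Of these genes 25 rose with library size scaling (median 0.94). Of 12 cytokine and chemokine genes 7 rose and 1 fell (8 and 2 adjusted over the list alone; median 0.90, adjusted p = 0.032, and adjusted p = 0.282 with an estimated correlation), with Tnfaip3 at 2.22 and Vcam1 at 1.37; the call was lost without KO replicate 1 (adjusted p = 0.06). All 3 measured neutrophil markers rose, S100a8 by 2.29, S100a9 by 1.82 and Csf3r by 1.70 (3 adjusted over the list alone; median 1.82, adjusted p = 0.032, and adjusted p = 0.282 with an estimated correlation). Of 5 T, NK and B cell markers 2 rose and 0 fell (2 and 0 adjusted over the list alone; median 0.69, adjusted p = 0.0853), the immunoglobulin genes Jchain (1.55) and Igkc (1.05). Erythroid markers were not called, with 1 of 7 higher and 3 lower (1 and 3 adjusted over the list alone; 1 and 2 without KO replicate 3; median -0.25, 0.11 with library size scaling; adjusted p = 0.219), Alas2 at -3.26 and Car2 at 2.47.

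Lists of drug metabolism and stress held opposite changes and were not called. Of 29 cytochrome P450 and drug metabolism genes 16 fell and 8 rose (18 and 9 adjusted over the list alone; median -0.75, mean 0.15, camera direction down, adjusted p = 0.0778; 0.0308 without KO replicate 3). Cyp2d9 fell by 2.21 on the log2 scale, while Cyp2b9 rose by 4.21 and the glutathione transferase gene Gstm3 by 4.85. Sex-biased liver genes fell in 10 of 17 cases and rose in 5 (10 and 5 adjusted over the list alone; median -0.35, 0.01 with library size scaling; adjusted p = 0.0763; 0.0456 without KO replicate 2). The ER stress and integrated stress response list had 11 of 22 lower and 4 higher (12 and 4 adjusted over the list alone; median -0.35, 0.01 with library size scaling; adjusted p of the list ER stress and integrated stress response 0.0778, and 0.0268 without WT replicate 2), with the unfolded protein response genes Xbp1 at -1.30 and Dnajb9 at -1.23 against Atf3 at 4.62. The NRF2 and oxidative stress list had 14 of 22 higher and 7 lower (14 and 7 adjusted over the list alone; median 0.64, adjusted p = 0.0778), with Srxn1 at 2.75 and the metallothionein gene Mt2 at -2.37.

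**Figure D2:**
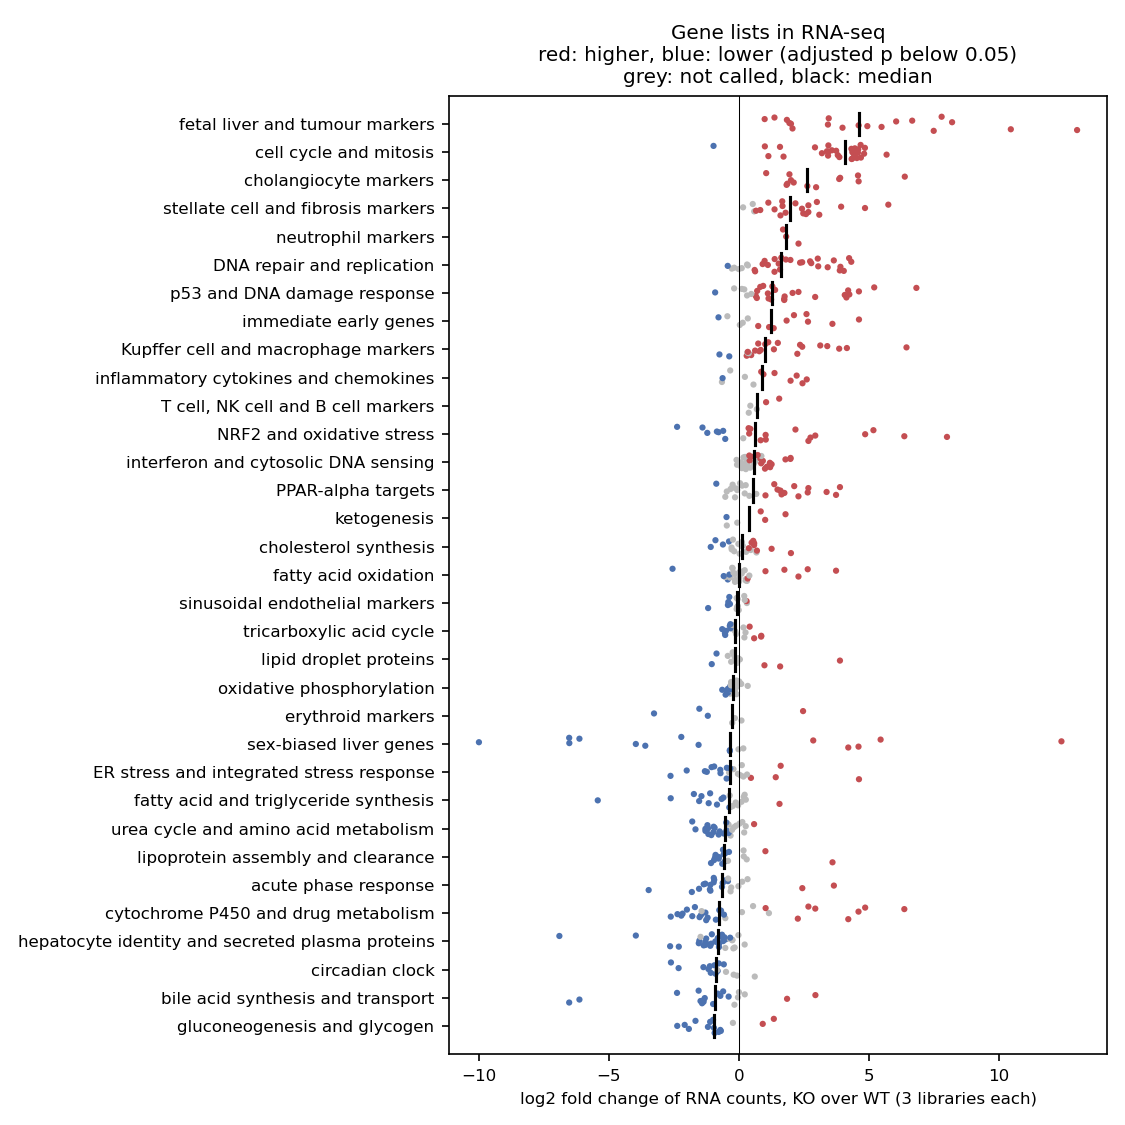
Log2 fold change of RNA counts, KO over WT (3 libraries each), for every measured gene of the fixed lists, 1 point per gene, red where called higher, blue where called lower and grey where not called (edgeR adjusted p 0.05), with black bars at list medians. Medians run from 4.60 for fetal liver and tumour markers to -0.95 for gluconeogenesis and glycogen, and the slightly negative medians of tricarboxylic acid cycle, lipid droplet, oxidative phosphorylation, erythroid, sinusoidal endothelial, sex-biased and ER stress lists turn positive with library size scaling.

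Called ATAC-seq peaks covered less of the genome in KO. ATAC-seq peaks covered 46.4 ± 5.81 Mb per library in WT and 37.9 ± 3.84 Mb in KO (SD, n = 6; two-sided exact permutation p = 0.0195). The number of peaks was 97928 ± 10170 in WT and 90685 ± 9549 in KO (exact permutation p = 0.236), a difference within the spread between libraries. The median peak width was 330 to 343.5 bp in KO libraries and 360 to 380 bp in WT libraries. Called peaks depend on the depth of a library, which was not tested, so covered length is not an amount of open chromatin. A larger share of KO peaks lay within 1 kb of a gene start, 19.9 ± 1.03% against 18.2 ± 1.31% in WT (exact permutation p = 0.0455; 0.0519 with a window of 2.5 kb). These 3 tests per assay were not adjusted for one another. Peak lists shared more sequence within genotypes than between them, with a mean Jaccard index of 0.655 against 0.586 (one-sided exact permutation p = 0.00216, the smallest that 462 splits allow).

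CUT&Tag lists of the histone marks and Pol II were longer on average in KO, without passing a test. H3K27ac lists held 74780 ± 12868 peaks in KO and 57682 ± 4600 in WT (SD, n = 3; exact permutation p = 0.2), and H3K9ac peaks covered 29.6 ± 7.39 Mb in KO and 18.7 ± 0.889 Mb in WT (exact permutation p = 0.1). H3K4me3 lists held 36548 ± 3768 peaks in KO and 30206 ± 2195 in WT (exact permutation p = 0.2), and Pol II lists 61206 ± 2285 and 54022 ± 2188 (exact permutation p = 0.1). Comparing 3 libraries with 3 cannot give an exact permutation p below 0.1. KO replicate 1 stood apart, with 85813 H3K27ac and 89262 H3K9ac peaks, the highest of their groups, and 2768 HNF4A and 3581 PPARa peaks, the lowest; without it the excess of H3K9ac peaks in KO was 2478 instead of 14133. Lists were more alike within genotypes for each antibody, for example H3K27ac with a mean Jaccard index of 0.602 within and 0.465 between genotypes and H3K9ac with 0.442 and 0.360 (one-sided exact permutation p = 0.1, the smallest possible).

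Regions open in 1 genotype were mostly open in WT. Of 164885 ATAC-seq regions, 5097 were WT-specific (present in at least 5 of 6 WT libraries and at most 1 KO library) and 1339 KO-specific by the mirror rule. Fisher's exact test per region gave 0 regions at an adjusted p under 0.05 (smallest 0.316) and 4513 at an unadjusted p under 0.05, of which 3657 were more often open in WT. With lists shortened to the same number of peaks, 3277 were WT-specific and 2269 KO-specific. Without WT replicate 6, the library with the fewest WT peaks, 7609 were WT-specific and 1396 KO-specific, and without it and KO replicate 1, which share another sequencing run code, 9423 and 1867. Leaving out a library loosens the rule by 1 library on that side, so these counts cannot be compared in size with those of all libraries. The largest change in RNA at a KO-specific promoter was at Gldn, which encodes the extracellular protein gliomedin. Its region (chromosome 9, 54285491 to 54287061, at the gene start) was open in 6 of 6 KO and 0 WT libraries, and its RNA rose by a log2 fold change of 7.56 (SE 0.66, edgeR adjusted p = 9.56e-06). At WT-specific promoters RNA went both ways: Sult2a8 (chromosome 7, 14446440 to 14447006) fell by 3.95 on the log2 scale, while Erich5 rose by 4.41 and Slc22a29 by 3.07.

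Regions carrying a mark in 1 genotype were mostly in KO. H3K27ac had 6083 KO-specific regions (3 of 3 KO and 0 WT libraries) and 1824 WT-specific regions, H3K9ac 3143 and 1143, Pol II 2458 and 1174, and H3K4me3 1166 and 381. With lists of the same length these were 3418 and 3549 for H3K27ac, 2040 and 2004 for H3K9ac, 1628 and 1617 for Pol II and 609 and 744 for H3K4me3, so KO-specific regions did not outnumber WT-specific ones for H3K27ac and H3K4me3 and did so by 36 for H3K9ac and 11 for Pol II. Leaving out a library loosens the rule and raises most counts, at most to 14740 H3K27ac and 6935 H3K9ac regions specific to KO without KO replicate 2, 2605 for H3K4me3 without KO replicate 3 and 4635 for Pol II without KO replicate 1. For WT-specific regions the highest were 3179 for H3K27ac without WT replicate 1, 2427 for H3K9ac without KO replicate 1, 2167 for Pol II without KO replicate 2 and 822 for H3K4me3 without WT replicate 3.

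Most regions specific to a genotype lay away from promoters, and those at promoters of named genes mostly went with the RNA. At promoters lay 44.6% of the KO-specific regions of H3K4me3, 25.04% of H3K9ac, 15.98% of H3K27ac and 13.1% of Pol II, and 6.74% to 11.1% of the WT-specific regions of these 4. Gldn was KO-specific for H3K4me3, H3K27ac, H3K9ac and Pol II as well as for ATAC-seq. The macrophage genes Gpnmb (H3K27ac region on chromosome 6, 49035579 to 49037612) and Trem2 (chromosome 17, 48346153 to 48348073) were KO-specific for H3K4me3, H3K27ac and H3K9ac. Prom1 and Spp1 were KO-specific for H3K4me3 and H3K27ac, and Col1a1 and Epcam for H3K4me3. Hsd3b5 (chromosome 3, 98629848 to 98630088) and Mup16 were WT-specific for H3K4me3, Mup7 and the fatty acid elongase gene Elovl3 for H3K27ac, and Elovl3 and Slco1a1 for H3K9ac. Hnf4a had H3K4me3 (chromosome 2, 163506686 to 163507981) and H3K9ac at its outermost annotated start in 3 of 3 KO and 0 WT libraries, while its RNA fell. Its RNA was high in WT without these marks there, so this start need not be the source of most of its RNA. Other starts of the gene were not examined. Wfdc3, a protease inhibitor family gene, was WT-specific for Pol II while its RNA rose by 6.48. Gpr182, an endothelial receptor gene, was KO-specific for Pol II, with a log2 fold change of Gpr182 of -0.34 (edgeR adjusted p = 0.0229) that was 0.022 with library size scaling and whose call was lost with DESeq2 (0.0857), without a filter (0.0681) and without WT replicate 1 (0.0529), WT replicate 3 (0.0625) or KO replicate 2 (0.0884). Of the 1339 KO-specific ATAC-seq regions, 179 overlapped a KO-specific and 0 a WT-specific H3K27ac region; of the 5097 WT-specific ones, 202 overlapped a WT-specific and 13 a KO-specific H3K27ac region.

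**Figure D3:**
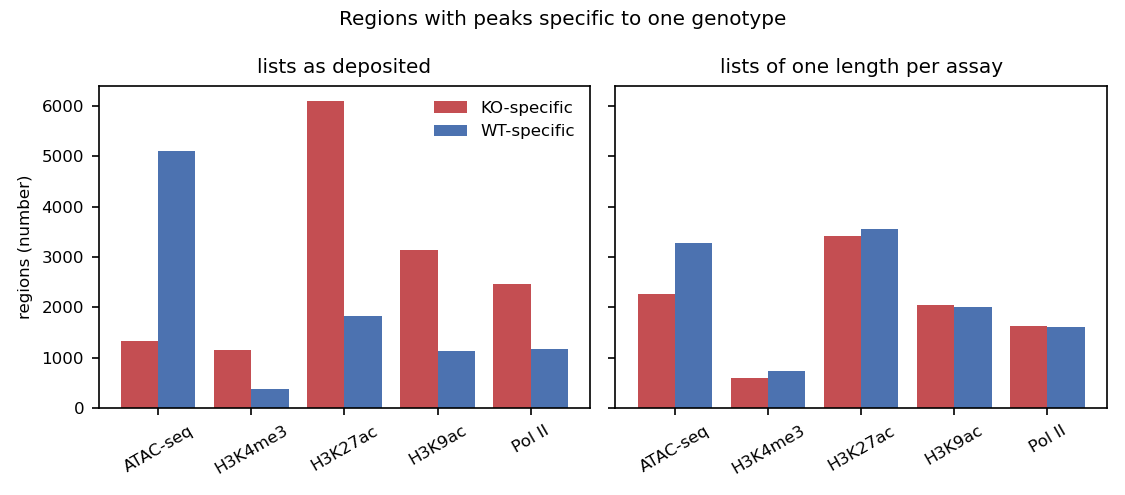
Number of regions specific to KO and to WT for ATAC-seq, H3K4me3, H3K27ac, H3K9ac and Pol II, from all peaks and with lists shortened to the same number of peaks. ATAC-seq has more WT-specific regions in both (5097 against 1339, and 3277 against 2269), while the excess of KO-specific H3K27ac regions (6083 against 1824) is absent with lists of the same length (3418 against 3549).

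HNF4A and PPARa lists were short and shared little between replicates. HNF4A lists held 4144 ± 347 peaks in WT and 3610 ± 777 in KO (SD, n = 3; exact permutation p = 0.5), and PPARa lists 6477 ± 912 and 6180 ± 2252 (exact permutation p = 1.0). Of the peaks of a library, 13.4% to 24.7% for HNF4A and 3.33% to 5.78% for PPARa were found in 1 given other library of the same genotype on average, against 72.1% to 93.4% for ATAC-seq. HNF4A had 80 WT-specific and 13 KO-specific regions. Without KO replicate 1, the shortest list, these were 84 and 158. Leaving out a library loosens the rule to 2 libraries on that side, which raises the count there. The turn therefore cannot be told from the looser rule, and this holds for PPARa below as well. With lists of the same length HNF4A had 65 WT-specific and 13 KO-specific regions. At -log10 q of at least 5 it had 55 and 5. PPARa had 14 WT-specific and 19 KO-specific regions, and 16 and 151 without KO replicate 1; without WT replicate 1 they were 137 and 26. HNF4A was WT-specific at the promoters of the carbonic anhydrase gene Car5a (RNA log2 fold change -2.02) and of Lbp (-0.95).

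Promoter occupancy of the gene lists was compared with that of all expressed genes. In ATAC-seq, promoters of sex-biased liver genes were open less often in KO, 48.0 ± 4.43% against 60.8 ± 3.04% in WT (SD, n = 6; exact permutation adjusted p = 0.0357), and those of bile acid genes 94.2 ± 2.04% against 99.2 ± 2.04% (exact permutation adjusted p = 0.0357; 0.606 with a window of 2.5 kb). No other list was called among 33. The sex-biased list joins genes whose RNA fell (10 of 17) and rose (5), so its lower occupancy does not stand for a change in 1 direction. Cyp2b9, whose RNA rose, had a promoter peak in 4 WT and 1 KO libraries. Slco1a1 and Elovl3, whose RNA fell, had one in 6 WT and 5 KO libraries, and Hsd3b5, whose RNA fell, in 6 and 6. Macrophage promoters were open in 52.2 ± 9.91% of KO and 36.2 ± 13.1% of WT cases (adjusted p = 0.171 by exact permutation; 0.0357 with a window of 2.5 kb). In CUT&Tag the exact test cannot pass the threshold; among the lists, cholangiocyte promoters with an H3K4me3 peak were 87.2 ± 4.44% in KO and 46.2% in each WT library, and cell cycle promoters with an H3K27ac peak 75.6 ± 20.4% and 33.3 ± 8.82% (SD, n = 3). All expressed genes went from 80.2% in WT to 86.2% in KO for H3K4me3 and from 63.5% to 76.8% for H3K27ac, so the differences beyond this were 35.0 and 28.8 points. Cholangiocyte promoters were also occupied more often in KO for H3K27ac (61.5% against 38.5% in WT) and H3K9ac (64.1% against 41.0%). They were not for ATAC-seq (52.6% in KO against 57.7% in WT) and Pol II (38.5% against 41.0%). Sinusoidal endothelial promoters, whose RNA list was not called, had a Pol II peak in 84.4 ± 7.70% of KO cases, a difference from WT of 41.8 points beyond that of all expressed genes (exact permutation adjusted p = 0.194).

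Expressed genes with a promoter occupied only in KO were higher in RNA. Genes that did not pass the filter on counts were left out, so the shares below do not hold for all specific promoters. A gene can pass through the counts of 1 genotype alone, and such a gene can move in 1 direction only. How much this adds to the changes below was not tested. Of 36 expressed genes with a KO-specific ATAC-seq promoter peak 30 rose and 0 fell at an edgeR adjusted p under 0.05 (median log2 fold change 1.55, camera adjusted p = 7.21e-09). The same sets were 281 genes for H3K4me3 (212 rose, 13 fell; median 1.93, adjusted p = 6.07e-24), 531 for H3K27ac (300 and 47; 0.74, adjusted p = 1.46e-10), 356 for H3K9ac (206 and 25; 0.90, adjusted p = 2.34e-12) and 141 for Pol II (109 and 1; 1.31, adjusted p = 5.94e-18). WT-specific promoters fell for H3K4me3 (6 of 7 genes, adjusted p = 0.000103), H3K27ac (11 of 13, adjusted p = 2.81e-05) and H3K9ac (12 of 17, adjusted p = 6.88e-06). All 8 calls were lost with an estimated correlation (adjusted p = 0.106 with an estimated correlation for H3K9ac in WT and 0.0935 for the others). The WT-specific sets of ATAC-seq (34 genes, 7 rose and 10 fell, adjusted p = 0.0866) and Pol II (33 genes, 7 and 13, adjusted p = 0.0947) were not called, nor were those of HNF4A (KO adjusted p = 0.147; WT 0.0717, with 1 gene of 9 risen and 4 fallen) and PPARa (KO 0.327, WT 0.295).

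Peaks of the single WT RPA1 list lay mainly at open chromatin and at Pol II regions. The WT RPA1 list held 10916 peaks and the KO list 3094, against 4019 for mouse IgG and 6940 for rabbit IgG; these 4 lists have no replicates, and the host species of the RPA1 antibody is not given, so which IgG is its control is unknown. Of the WT RPA1 peaks, 66.8% (exact 95% interval 65.9 to 67.7) overlapped ATAC-seq regions present in all WT libraries, against at most 2.98% in 100 shuffles. The overlap was 65.5% with Pol II, 54.9% with H3K27ac, 44.9% with H3K9ac, 43.6% with H3K4me3, 4.15% with HNF4A and 0.623% with PPARa regions, and 31.3% lay within 1 kb of a gene start. The mouse IgG list came near or above this for promoters (26.4%), HNF4A (3.38%) and PPARa (0.946%), and the KO RPA1 list was above it for PPARa (0.937%). Of the WT RPA1 peaks 3.58% (3.24 to 3.95; at most 0.119% in shuffles) overlapped a peak of the KO RPA1 list, 7.21% (6.73 to 7.71) one of mouse IgG and 2.55% (2.26 to 2.86) one of rabbit IgG; the KO list is shorter, and 12.6% (11.5 to 13.9) of its peaks overlapped a WT RPA1 peak. The same ATAC-seq regions held 23.3% of the KO RPA1, 38.5% of the mouse IgG and 8.98% of the rabbit IgG peaks. Mouse IgG peaks overlapped Pol II regions in 37.1%, H3K27ac in 26.4%, H3K9ac in 24.4% and H3K4me3 in 24.8%. Rabbit IgG peaks did so in 7.68%, 6.35%, 5.42% and 4.77%. In shuffles the mouse IgG list reached at most 2.44% for these 4. Part of this location is therefore shared with a control list and is not particular to RPA1. RPA1 peaks lay in 6753 of 48319 ATAC-seq regions open in all 12 libraries, in 0.608% of WT-specific (0.414 to 0.862) and in 0.299% of KO-specific regions (0.0815 to 0.763). Intervals cover counting error of the lists only, and the numbers compare these libraries, not the genotypes.

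**Figure D4:**
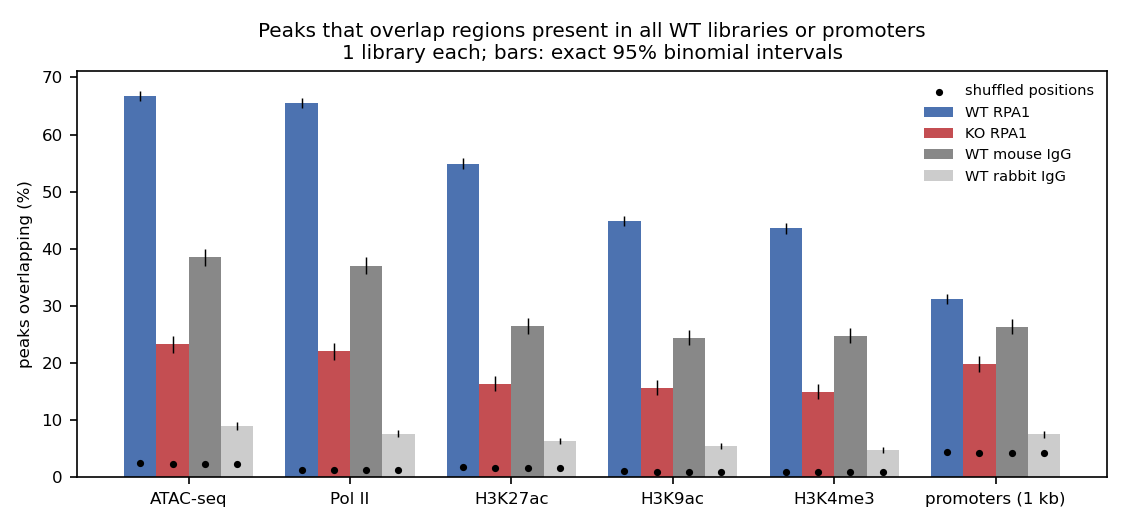
Percent of peaks of the WT RPA1, KO RPA1, mouse IgG and rabbit IgG lists (1 library each) that overlap regions present in all WT libraries of each assay, with exact 95% binomial intervals. WT RPA1 peaks overlap ATAC-seq regions in 66.8% of cases, against 38.5% for mouse IgG, 23.3% for KO RPA1 and 8.98% for rabbit IgG.

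Genes with an RPA1 peak at the promoter in WT were lower in KO than other genes. Of 2206 expressed genes with a WT RPA1 promoter peak and no KO RPA1 or IgG peak there, 743 fell (33.7%) and 279 rose (12.6%), with a median log2 fold change of -0.18 (camera of limma p = 4.12e-06 with the preset correlation; p = 0.052 with an estimated correlation, where the call was lost). Of the other 10734 tested genes 19.4% fell and 28.4% rose (median 0.05). The median is smaller than the shift of 0.37 between scalings, so its sign depends on the scaling, whereas the difference from other genes does not. Among genes with an ATAC-seq promoter peak in all WT libraries, 276 of 2198 RPA1 genes rose and 742 fell. Of 8432 other genes with such a peak, 2105 rose and 1738 fell. Other genes that pass the filter through KO counts alone can only rise. Expression level was not matched, and genes with an IgG promoter peak were not tested as a control. The difference therefore cannot be tied to RPA1 rather than to activity of these genes in WT.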

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

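Of the tests in this part, those of exchanged genotype labels and of other splits for gene lists, promoter sets and RPA1 promoter genes were set before their results were seen, and the other tests were chosen afterwards.

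ATAC-seq WT replicate 6 had 78875 peaks, far below the other WT libraries: its gap to the next, divided by the range of the 6, was 0.651. It was the only value among 6 group measures of ATAC-seq past Dixon's limit, and groups of 3 were not tested. Its file name carries another code than those of the other WT libraries, as does that of KO replicate 1. This code was read here as that of a sequencing run. Each genotype has 1 such library, and no term for the run was fitted. Without both, 9423 regions were WT-specific and 1867 KO-specific, so the excess stayed in WT. The rule then asks for 1 library fewer in each genotype, which raises both counts. The size of the excess can therefore not be compared with that of all libraries.

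Rpa1 counts were equal in both genotypes (log2 fold change -0.03). Exchange of the RNA-seq labels as a whole would make genes with a KO-specific ATAC-seq promoter lower in KO, but their median was 1.55 (camera adjusted p = 7.21e-09; adjusted p = 0.0935 with an estimated correlation). A single WT library labelled KO is excluded by the correlations, since the lowest between KO libraries exceeded the highest between a KO and a WT library by 0.0802. That the transcripts came from cells that kept the gene, or from an allele that is transcribed but not translated, may be so, and the whole-gene value of -0.026 cannot tell. The genotypes differed in 6157 genes, so a biological difference between the groups stays open, as untested on Rpa1 protein.

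Markers of cholangiocytes, stellate cells and macrophages rose (median 1.87 over 57 markers) together with cell cycle and fetal liver genes, while hepatocyte genes fell. A lower share of hepatocytes alone would raise every other cell type alike, but sinusoidal endothelial markers had a median of -0.06 (15 markers). The difference was 1.93 (two-sided permutation p = 0.00099, over genes, which are not independent replicates). The lists on both sides were picked after their changes were seen, so this p cannot decide against a lower share. Lists left out of the contrast had medians of 1.82 (neutrophil), 0.69 (T, NK and B cell) and -0.25 (erythroid markers). Promoters of the same endothelial markers went the other way, with a Pol II peak more often in KO by 41.8 points and an H3K9ac peak by 16.5 points beyond all expressed genes (exact permutation p = 0.1, the smallest possible). A lower hepatocyte share, as all or part of the cause, and a change in endothelial cells therefore stay open. The median of the 57 was 2.24 with library size scaling, so the rise did not come from the composition scaling used. Library size scaling shifts all genes up by about 0.37 and could only raise this median, so it tests no other error of scaling. More cells of these types, or expression of their markers by hepatocytes, may each be the source; whole tissue cannot separate these.

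More regions were KO-specific than WT-specific for the histone marks and Pol II, and more were WT-specific in ATAC-seq. Longer lists in KO may be the cause for the marks: with lists of the same length the KO share of specific regions was 45.0% for H3K4me3, 49.1% for H3K27ac, 50.4% for H3K9ac and 50.2% for Pol II. Shortening pulls counts together, and an excess as large came from other splits (H3K4me3 135 against up to 168, H3K27ac 131 against 139, H3K9ac 36 reached by 7 of 9, Pol II 11 reached by 9 of 9), so this stays open. For ATAC-seq, longer lists in WT are excluded as the whole cause, since the WT share was 59.1% and the excess of 1008 was above the 660 reached in 99 other splits. A biological difference in chromatin between genotypes is a candidate explanation for ATAC-seq, and depth of the libraries, not given in the peak lists, was not tested.

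Other splits of the libraries were compared with the real one. For ATAC-seq regions chance can be excluded: 1 of 100 splits, the real one, gave as many as 6436 specific regions, and the highest other gave 2928. For the other results the 10 splits are too few for a share under 0.05. As large a result came from 1 split, the real one, for genes called (6157, highest other 0), for RPA1 promoter genes (camera of limma with the preset correlation, p = 4.12e-06, lowest other 2.28e-05) and for regions of H3K4me3 (1547, 441), H3K27ac (7907, 1057), H3K9ac (4286, 1417), Pol II (3632, 846), HNF4A (93, 79) and PPARa (33, 29). It came from 2 splits for gene lists (21, highest other 21) and from 5 for promoter sets (8, highest other 9). Camera with its preset correlation thus called as many lists in a split that mixes the genotypes. Each other split still sets 2 libraries of a genotype against 1, so this does not measure how many of its calls are false. The list calls depend on how correlation between genes is treated. None passed with the estimated correlation, while fry called lists in both directions. As fry does not compare a list with other genes and 6157 genes were called, its calls do not offset that loss.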

How the results depend on the processing

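Among the tests in this part, library size scaling, ATAC-seq without WT replicate 6, a background of open promoters for RPA1 genes and promoter sets from lists of the same length were chosen after the results were seen. Unless a cause is given, the cause was not tested.

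In RNA-seq, libraries of the same replicate number were not more alike after removal of group means (correlations -0.036, 0.016 and 0.052), and neither were libraries of ATAC-seq (-0.00667 to 0.0477 over same-numbered pairs), in the presence of peaks over regions. For CUT&Tag such pairs gave -0.0358 to 0.0727. For H3K4me3 all of them (0.0111 to 0.0727) lay above every other pair (-0.0596 to 0.00622), so a factor shared by number stays open there. For no other antibody did all same-numbered pairs lie above the others. With a replicate block, 142 of 142 named genes and 33 of 33 lists kept their direction and side of the threshold, and 3199 genes were higher and 2691 lower. The ATAC-seq differences kept their direction but not their call, with exact sign-flip p = 0.0625 for covered length (-8.56 Mb) and 0.0938 for promoter share (1.62 points); 6 pairs allow no p below 0.0313.

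In RNA-seq KO against WT, genes called, higher in KO, were 2886 to 3971 (and in RNA-seq KO against WT, genes called, lower in KO, 2400 to 2882) with DESeq2 size factors, DESeq2, limma-voom, no filter and a mean count of 10, 2088 and 791 at an absolute log2 fold change of at least 1, and 5524 and 1163 with library size scaling, which leaves the 0.37 shift of all genes in. Of 142 named genes, 129 were the same with library size scaling, 10 lost and 2 gained a call, and Gpr182, an endothelial receptor gene, reversed from -0.34 to 0.022. Camera with an estimated correlation called 0 lists higher and 0 lower (lowest adjusted p = 0.259), where the main test called 12 and 9; fry called 16 and 12. Leaving out 1 library gave 2799 to 3516 genes higher, 2252 to 2734 lower, 11 to 12 lists higher and 8 to 10 lower.

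ATAC-seq promoter share differed by 1.56 points with a 2.5 kb window (exact permutation p = 0.0519). With lists of the same length, KO- and WT-specific regions were 2269 and 3277 for ATAC-seq, 609 and 744 for H3K4me3, 3418 and 3549 for H3K27ac, 2040 and 2004 for H3K9ac, 1628 and 1617 for Pol II and 12 and 14 for PPARa; shorter lists in the genotype with more peaks are built into this. HNF4A had 13 KO-specific and 65 WT-specific regions with lists of the same length. Requiring 6 of 6 against 0 libraries in ATAC-seq gave 185 and 943, and leaving out both libraries of the other run 1867 and 9423. At -log10 q of at least 5, HNF4A had 5 KO-specific regions and PPARa 5 KO- and 7 WT-specific ones. With at least 50% of the region covered, H3K9ac had 5041 KO-specific regions and PPARa 11 and 7. Counting all contigs, or leaving out regions with a rabbit IgG peak, kept each count within 1.5 times. Without WT replicate 6, ATAC-seq had 1396 and 7609. Leaving out ATAC-seq libraries loosens their rule on that side, which raises the counts.

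Leaving out 1 CUT&Tag library loosens the rule to 2 libraries on that side. KO-specific regions then were 1320 to 2605 for H3K4me3, 6931 to 14740 for H3K27ac, 3910 to 6935 for H3K9ac, 3124 to 4635 for Pol II, 21 to 158 for HNF4A and 26 to 151 for PPARa, and WT-specific ones 505 to 822, 2035 to 3179, 1339 to 2427, 1603 to 2167, 84 to 222 and 16 to 137.

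ATAC-seq promoters of 0 lists were called higher and 2 lower; with 2.5 kb it was 1 and 1, and with lists of the same length 3 and 12. Of these 15, 7 had the same value (-0.85, adjusted p = 0.011) because none of their own promoters changed and only the share of all expressed genes did; fatty acid and triglyceride synthesis reversed to this value from 0.44. All 8 called promoter sets lost their call with an estimated correlation (adjusted p = 0.0935, H3K9ac in WT 0.106). WT-specific ATAC-seq promoters gained one with lists of the same length (adjusted p = 0.00765), and HNF4A ones with 2.5 kb (0.00825). RPA1 promoter genes had camera p = 4.05e-06 with 2.5 kb, 5.86e-07 at -log10 q of at least 5, 4.29e-05 against open promoters and 0.052 with an estimated correlation.

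WT RPA1 peaks at -log10 q of at least 5 overlapped KO RPA1 in 5.18%, mouse IgG in 10.2%, rabbit IgG in 3.29%, ATAC-seq in 77.2%, H3K4me3 in 53.5%, H3K27ac in 65.2%, H3K9ac in 54.5%, Pol II in 76.4%, HNF4A in 6.35%, PPARa in 0.992% and promoters in 36.0%. With at least 50% of the peak covered, overlap was 1.93% with KO RPA1, 4.02% with mouse IgG, 1.21% with rabbit IgG, 38.6% with H3K4me3, 49.7% with H3K27ac, 40.9% with H3K9ac and 3.67% with HNF4A. The KO RPA1 list, with 579 peaks at -log10 q of at least 5, then overlapped ATAC-seq in 38.7%, HNF4A in 6.74%, promoters in 32.6% and the WT RPA1 list in 28.2%. Data simulated at this depth with 3 libraries per group had 66% of genes changed by a log2 fold change of 1 found. Far fewer genes were changed in the simulation than were called in the data, and what limits this share was not tested apart.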

Other observations

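All tests of imprinted and sex-biased genes in this part were chosen after the results were seen, and the genes named here were chosen after their values were seen.

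H19, Meg3 and Rian, non-coding RNAs of imprinted clusters, stood out among the risen genes (log2 fold changes 13.00, 4.58 and 4.66), so a list of imprinted genes was written. Outside the clusters of these 3, which also hold Igf2, 10 of 15 measured imprinted genes rose and 1, Slc38a4 (-0.80), fell, with a median of 1.05 (camera p = 0.00288; p = 0.0335 with an estimated correlation). Grb10 (2.16) and Peg3 (2.11) were among those that rose. A rise shared by imprinted genes of several clusters is therefore a candidate explanation, as a hypothesis found and tested on the same data. Markers of stellate cells, cholangiocytes and macrophages rose in the same libraries (medians 1.99, 2.63 and 1.01), so a change in cell types is another candidate source; the 2 were not tested apart, and methylation was not measured.

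All 8 genes of a male-biased list fell (median -5.04) and all 5 measured genes of a female-biased list rose (median 4.60). Several of them had been noticed among the largest changes, so no test of this pattern is given. Female animals among the KO libraries are excluded as its source, since 4 Y chromosome genes had a median of -0.18.

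RNA-seq libraries correlated at 0.977 to 0.982 within KO, 0.979 to 0.983 within WT and 0.859 to 0.897 between genotypes. KO replicate 3 was nearest to WT (0.894 to 0.897).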
